A study of Homo sapiens with 6 samples.

How the data were processed

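Total RNA of 6 samples of A375 melanoma cells, 3 given DMSO and 3 given 3 µM vemurafenib for 24 h, was purified, copied into biotin-labelled RNA and hybridised to Illumina bead arrays, per the labels' protocols. The authors deposited a table with a signal intensity for each of 48107 probes on each array, on a linear scale with neither background subtraction nor normalization between arrays, as the values show. Beside each intensity the deposited table gives a detection p-value; per the file headers it is a detection p, and how it was computed is not given in the sources used here. A further deposited table of the series holds log2 values of the same arrays. Its method and scale are not stated; set against the intensities, these values are log2 signals after quantile normalization with no background correction, from which they differ by at most 0.0513 (92.6% of values within 0.03), and each array has a median of 6.54. The scanner software and its version are not given in the sources used here.

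The intensities were the main input. A probe was left out where a value was missing (4 probes). Background was corrected with limma 3.58.1 in R 4.3.3 by the normexp model, with the negative control level inferred from the detection p-values since control probes are not labelled in the tables used; an offset of 16 was added, and the arrays were quantile normalized and put on the log2 scale. The inferred background had a mean of 85.0 to 88.3 and an SD of 4.54 to 5.36 intensity units, close to the median signal, so genes expressed at low levels are measured with compressed differences. Probes with a detection p under 0.01 on at least 3 of the 6 arrays were kept, which left 18747. Probe names came from GEO's platform annotation: 30111 probes had 1 gene symbol, 8 several and 17984 none, and 30072 of the named probes matched a current gene table by gene identifier, which changed 0 symbols. A gene with several kept probes was represented by the probe with the highest mean over all 6 arrays, which gave 11220 genes. Of 2807 genes with 2 or more kept probes, 0 had probes that changed in opposite directions. 1 gene that the naming rule lists has no probe under its name in the tables used and is not analysed here.

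The groups were compared with limma's lmFit and eBayes as vemurafenib minus DMSO, over all 6 samples and without covariates, and p-values were adjusted by the Benjamini-Hochberg method over all kept probes, with a threshold of 0.05. Adjusted p-values of single genes are from this fit. Errors are SDs over the 3 samples of a group or standard errors of the log2 difference. A gene not detected on any array of a group was called not well above background there. Its fold change is given as at least the brighter group's mean over a floor, which on each array is the higher of the lowest signal among detected probes and the gene's own signal. A gene detected on some arrays of the dimmer group keeps its fitted change, which is then approximate. This holds for TCN1, MCM10, CTSK, SNAI2, ROBO4 and CYP1B1, each detected on 1 of 3 such arrays. It also holds for CLIC3, MAP1LC3C, NUPR1, COL13A1, ETV4, RRM2, RBL1, DSP and LYZ, each detected on 2. Gene lists were tested with limma's camera at a preset correlation of 0.01, over 1 probe per gene, with adjustment over the 26 of 29 lists that had at least 5 measured members; camera with an estimated correlation and fry were alternatives. With an estimated correlation, the call of ERK-driven transcription held and the other 9 of 10 calls did not. Neither of these alternatives used the replicate number as a block, nor did the fits with a sample left out. Camera with the replicate block was run at the preset correlation only. The lists were ERK feedback regulators, ERK-driven transcription, immediate early genes, DNA replication and S phase, mitosis and G2/M, cell cycle arrest and quiescence, melanocyte differentiation, neural crest and dedifferentiated state, stem cell and drug tolerance genes, SRC and STAT3 signalling, receptor tyrosine kinases, their ligands, the BCL2 family, p53 targets, glycolysis, oxidative phosphorylation, lysosome and autophagy, cholesterol synthesis, ribosome biogenesis and MYC targets, amino acid and integrated stress response, interferon response, antigen presentation, YAP and TEAD targets, matrix, proteases and invasion, housekeeping genes, and markers of fibroblasts, keratinocytes, leukocytes and endothelium. Some genes stand in more than 1 list.

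The lists, the tests, the alternatives and the rule for naming genes were fixed before the data were examined. The rule names the 10 largest rises and the 10 largest falls among passing genes whose 3 treated values all lie on one side of the 3 controls and that were detected on all 3 arrays of the higher group, leaving out placeholder symbols; the genes of the title and the drug's target; from each list up to 4 passing members with the largest change, or up to 2 of the most abundant if none passes; and ACTB and GAPDH. List members named beyond this rule were chosen after their values were seen.

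Both groups use the same replicate numbers, so it was checked whether samples of the same number deviate together from their group means. The correlations of the deviations over genes were 0.189 for the unnumbered pair, 0.351 for pair 1 and 0.523 for pair 2, all above 0.1, so the numbers were taken to pair the samples. The pairing rests on these values and not on a statement in the labels, and both unnumbered samples correlated more with the 1 sample of the other group than with each other (0.352 for DMSO unnumbered with vemurafenib 1 and 0.26 for DMSO 1 with vemurafenib unnumbered, against 0.189). The values therefore set the 2 pair apart but do not single out the other pairs. The first principal component (63.4% of the variance) separated the groups and the second (19.8%) separated both samples numbered 2 from the rest. The SD of the log2 differences between the unnumbered and 1 samples was 0.298 (DMSO) and 0.321 (vemurafenib), and between either and the 2 sample of its group 0.534 to 0.556.

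The alternatives were no background correction, normexp with an offset of 50, median centring, the deposited log2 values, no filter, a detection p under 0.05 on 3 arrays or under 0.01 on all 6, eBayes with trend and robust options, the replicate number as a block, each sample left out in turn, the mean of a gene's probes, an adjusted p under 0.01, limma's treat with a minimum fold of 1.2, and the other list tests. Leaving out both samples numbered 2, and averaging the unnumbered and 1 samples of each group, were added after seeing the data. The limma fit was tested on simulated log2 values for the comparison of vemurafenib with DMSO (18747 probes, 200 of them changed, 10 runs). It recovered 32.1% of probes changed by 1 on the log2 scale and 82.5% of those changed by 2, and 3.94% of its calls were false. Background correction, normalization, the filter and the choice of a probe per gene were not simulated. The simulated noise was independent between samples, while the unnumbered and 1 samples lay close together. The share of false calls therefore need not hold for the real data. Figures were drawn with matplotlib 3.10.9.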

Results

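The series measured messenger RNA in A375 cells, an established human melanoma line whose growth depends on signalling from RAF through MEK to ERK. Cells received the solvent DMSO (n = 3 samples) or 3 µM vemurafenib, an inhibitor of RAF-family kinases, for 24 h (n = 3 samples). The question was which genes differ after a day of drug, with SOX2 and CD24, which the series title names, as the genes of first interest. Each sample was hybridised to 1 array, so 6 arrays limit the precision of every value. Median signals lay between 91.0 and 94.5 intensity units against a mean background of 85.0 to 88.3, and between 18370 and 20044 probes per array (38.2% to 41.7%) were detected. The labels number the samples of each group as unnumbered, 1 and 2. They do not say that these were separate cultures, so p-values measure the spread between these samples, which may be technical.

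After 24 h of vemurafenib, CD24, a small surface glycoprotein, rose 11.1-fold. Its normalised log2 intensity went from 5.0 ± 0.07 to 8.47 ± 0.73 (SD, n = 3 per group). SOX2, a transcription factor of neural and pluripotent stem cells, rose 8.45-fold, from 6.54 ± 0.21 to 9.62 ± 0.44 (SD, n = 3 per group). The log2 changes were 3.47 ± 0.33 (SE) for CD24 and 3.08 ± 0.25 (SE) for SOX2, with limma adjusted p-values of 0.00194 and 0.00122. Some processing alternatives gave smaller changes for both genes, and the ranges are given in the section on processing. All 3 treated samples lay above all 3 control samples for both genes, and both calls held without each array in turn. An exact two-sided permutation test gave p = 0.1 for each gene, which is the smallest p that 3 samples against 3 allow. A second SOX2 probe also rose, by 2.78 on the log2 scale (limma adjusted p = 0.00352). A second CD24 probe was not well above background in either group (log2 4.29 ± 0.10 and 4.52 ± 0.13, SD, n = 3 per group) and gives no fold change.

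**Figure D1:**
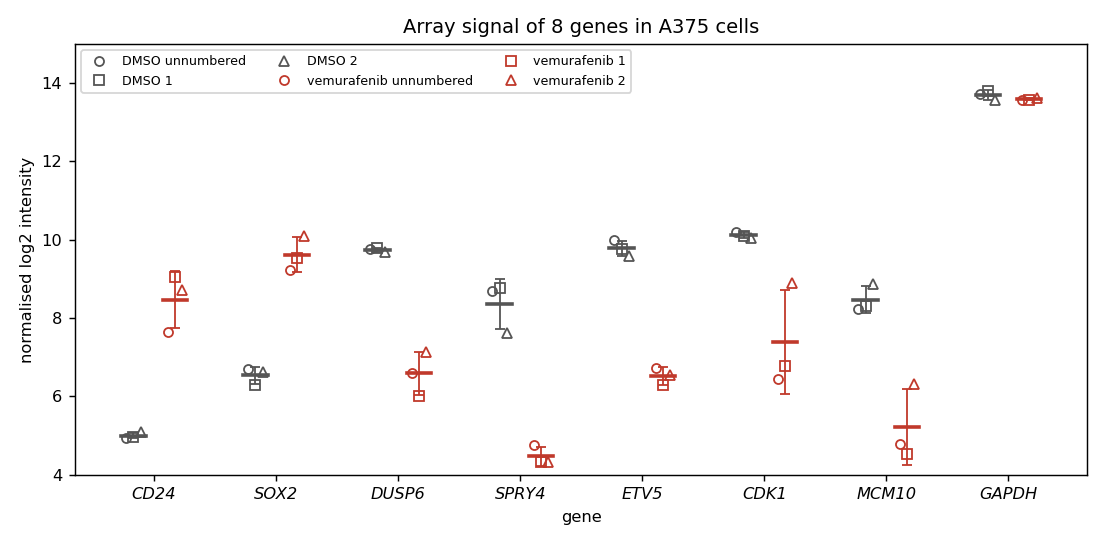
Normalised log2 intensity (vertical axis) of 8 genes (horizontal axis) on the 6 arrays, with DMSO in grey and vemurafenib in red, where symbols mark the unnumbered, 1 and 2 samples, thick lines the group means and bars 1 SD (n = 3 per group). CD24 and SOX2 lie higher in all treated samples, and DUSP6, SPRY4, ETV5, CDK1 and MCM10 lie lower. For DUSP6, CDK1 and MCM10 the treated sample 2 stands nearest to the controls, and for SPRY4 and ETV5 it does not.

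Across the transcriptome, 1800 of 11220 genes tested changed at a limma adjusted p under 0.05, of which 908 rose and 892 fell. At the level of probes 1314 rose and 1402 fell, and 3962 genes had an unadjusted p under 0.05. The 3 treated values lay wholly above or below the 3 control values for 4474 genes (39.9%). By chance 10% would be expected if the 6 samples were independent. That is not known here, since the unnumbered and 1 samples of each group may be technical repeats. How far the share exceeds chance therefore stays open. A change of at least 2-fold was seen for 1002 genes (471 higher, 531 lower), and 61 genes rose and 94 fell by at least 4-fold. The largest rises included SCRG1, a small secreted protein (at least 13.1-fold, adjusted p = 0.00129), TCN1, a cobalamin-binding protein detected on 1 of 3 control arrays (14.0-fold, adjusted p = 7.45e-04), PPP2R2B, a regulatory subunit of protein phosphatase PP2A (10.2-fold, adjusted p = 5.49e-04), and ID2, an inhibitor of DNA-binding helix-loop-helix factors (8.84-fold, adjusted p = 0.00279). SAMD11 rose at least 10.5-fold and ANGPTL7, a secreted angiopoietin-like protein, at least 7.81-fold. MGP, an inhibitor of calcification, rose by 3.38 ± 0.90 (SE) on the log2 scale, CLIC3, a chloride channel protein, by 3.32 ± 0.54, and MAP1LC3C, an autophagosome protein, by 3.15 ± 0.82. The largest falls were those of CEMIP, a hyaluronan-binding protein (at least 54.0-fold, adjusted p = 6.13e-05), the neutrophil-attracting chemokine CXCL8 (26.9-fold, adjusted p = 5.98e-04) and ESM1, a secreted proteoglycan (26.6-fold, adjusted p = 0.00123). They were followed by SPRY4 (at least 14.1-fold), FOSL1 (14.0-fold), the membrane protein TMEM158 (10.9-fold), CDC45 (10.9-fold), the transmembrane collagen COL13A1 (10.3-fold), the surface nucleotidase NT5E (10.1-fold) and ETV4 (10.1-fold). Among these 20 genes, leaving out single arrays ended the calls of MGP (4 arrays, adjusted p up to 0.155), MAP1LC3C (5 arrays, up to 0.143), CDC45 (5 arrays, up to 0.0896) and CLIC3 (without the unnumbered vemurafenib sample, 0.0570).

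The direction of the 1800 genes was the same without each array, which their choice from these same arrays makes nearly certain. The number of genes passing the test depended on the samples used. It was 410 without DMSO unnumbered, 608 without DMSO 1, 1166 without DMSO 2, 307 without vemurafenib unnumbered, 394 without vemurafenib 1 and 2670 without vemurafenib 2. With the replicate number as a block in limma, 3344 genes changed (1813 higher, 1531 lower), all 1800 among them. Without the 2 samples numbered 2, which stood apart from the others in both groups, 3649 genes changed. The unnumbered and 1 samples of each group lay close together and may be technical repeats; with them averaged, 2 samples against 2, 26 genes changed. When each array was centred on its median in place of quantile normalization, 1019 genes rose and 658 fell (60.8% higher, against 50.4%).

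Most genes that report ERK signalling fell. Of the 8 measured feedback regulators of the pathway, phosphatases and adaptors that ERK induces against itself, 7 fell, also 7 when adjusted over the list alone, and SPRY1 did not pass (log2 change -0.02). DUSP6, the cytoplasmic ERK phosphatase, fell 8.92-fold from log2 9.75 ± 0.06 to 6.59 ± 0.56 (SD, n = 3 per group; limma adjusted p = 0.00132). SPRY4 fell at least 14.1-fold, SPRY2 6.84-fold and DUSP5 3.91-fold. The list's median log2 change was -1.92 (camera adjusted p = 1.57e-07; adjusted p = 0.239 with an estimated correlation). Of 27 measured genes of ERK-driven transcription, 17 fell and 10 did not pass (18 fell when adjusted over the list alone; 1 rose and 18 fell with the replicate block). They included CXCL8, the AP-1 subunit FOSL1, and the ETS factors ETV4 and ETV5 (log2 changes of -4.75, -3.81, -3.33 and -3.25, limma adjusted p-values of 5.98e-04, 0.00185, 5.49e-04 and 5.49e-04), and also MYC (-2.70) and cyclin D1, CCND1 (-2.77). Their median was -1.14 (camera adjusted p = 1.84e-13), and this was the list whose call held with an estimated correlation (adjusted p = 0.0442). The calls of the 8 genes named by rule from both lists held without each array in turn, and the 17 falls of the second list were 11 without vemurafenib unnumbered. Both lists fell in each replicate pair, with medians of -2.09, -2.21 and -1.47 for the feedback regulators and -1.23, -1.16 and -1.55 for ERK-driven transcription in the unnumbered, 1 and 2 pairs.

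The immediate early genes, fast-responding transcription factors, were mixed. Of 18 measured, 1 rose, 4 fell and 13 did not pass (2 and 7 when adjusted over the list alone). KLF2, KLF6 and IER5 fell, with log2 changes of -1.67 ± 0.27, -1.0 ± 0.21 and -0.69 ± 0.18 (SE), while the stress factor ATF3 rose by 1.16 ± 0.24. Their limma adjusted p-values were 0.0113, 0.0236, 0.0431 and 0.0231. FOS (log2 change 0.95, adjusted p = 0.378) and EGR1 (-1.27, adjusted p = 0.171) did not pass, and the list's camera adjusted p was 0.123. With the replicate block 3 rose and 7 fell. Of the 4 genes named by rule, 0 passed without each array in turn (adjusted p up to 0.133), and leaving out either the unnumbered or the 1 sample of vemurafenib ended each of the 5 calls.

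Most genes of cell division fell. Of 51 measured genes of mitosis and G2/M, 44 fell (49 when adjusted over the list alone), 6 did not pass, and CDC25B, a phosphatase that activates cyclin-dependent kinases, rose (log2 change 0.57). CDK1, the mitotic kinase, fell 6.63-fold, from log2 10.11 ± 0.08 to 7.38 ± 1.33 (SD, n = 3 per group; limma adjusted p = 0.0228), the kinesin KIF14 5.95-fold, cyclin A2, CCNA2, 5.85-fold, and the centromeric histone CENPA 5.83-fold. The list's median log2 change was -1.75 (camera adjusted p = 2.28e-19; adjusted p = 0.524 with an estimated correlation). Of 43 measured genes of DNA replication and S phase, 31 fell and 12 did not pass (39 fell when adjusted over the list alone). The helicase factors CDC45 and MCM10, the nuclease EXO1 and the ribonucleotide reductase subunit RRM2 fell, with log2 changes of -3.45, -3.26, -3.09 and -2.92 (limma adjusted p-values of 0.0231, 0.00680, 0.0179 and 0.0112). The median was -1.56 (camera adjusted p = 6.44e-18; adjusted p = 0.524 with an estimated correlation). The vemurafenib sample 2 lay above the other treated samples by a median of 1.57 (log2) over the mitosis list and 0.88 over the S phase list, and the DMSO sample 2 above the other controls by 0.15 and 0.59. The mitosis median was -2.32, -2.18 and -0.78 in the unnumbered, 1 and 2 pairs, and the S phase median -1.63, -1.65 and -1.32. The 44 falling mitosis genes became 1, 3, 13, 0, 1 and 50, and the 31 S phase genes 10, 17, 16, 7, 9 and 38, when DMSO unnumbered, 1 and 2 and vemurafenib unnumbered, 1 and 2 were left out in turn; without a filter on dim probes they were 1 and 11. With the replicate block and all arrays, 50 mitosis genes fell and 1 rose, and 39 S phase genes fell. Of the 8 genes named here by rule, MCM10 passed without each array in turn.

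Genes of ribosome biogenesis and other MYC targets also fell in part. Of 34 measured, 18 fell and 16 did not pass (29 fell when adjusted over the list alone, and 31 with the replicate block). NOP16 fell 3.36-fold, NOLC1 2.66-fold, MRTO4 2.63-fold and dyskerin, DKC1, 2.44-fold (limma adjusted p-values of 0.0333, 0.0152, 0.0219 and 0.0345). The median log2 change was -0.85 (camera adjusted p = 3.98e-12; adjusted p = 0.524 with an estimated correlation). Both samples numbered 2 lay above the others of their group over this list, by medians of 0.47 (DMSO) and 0.64 (vemurafenib). The 18 falling genes became 0, 1, 4, 0, 1 and 27 without DMSO unnumbered, 1 and 2 and vemurafenib unnumbered, 1 and 2 in turn, 4 without a filter and 12 with median centring.

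**Figure D2:**
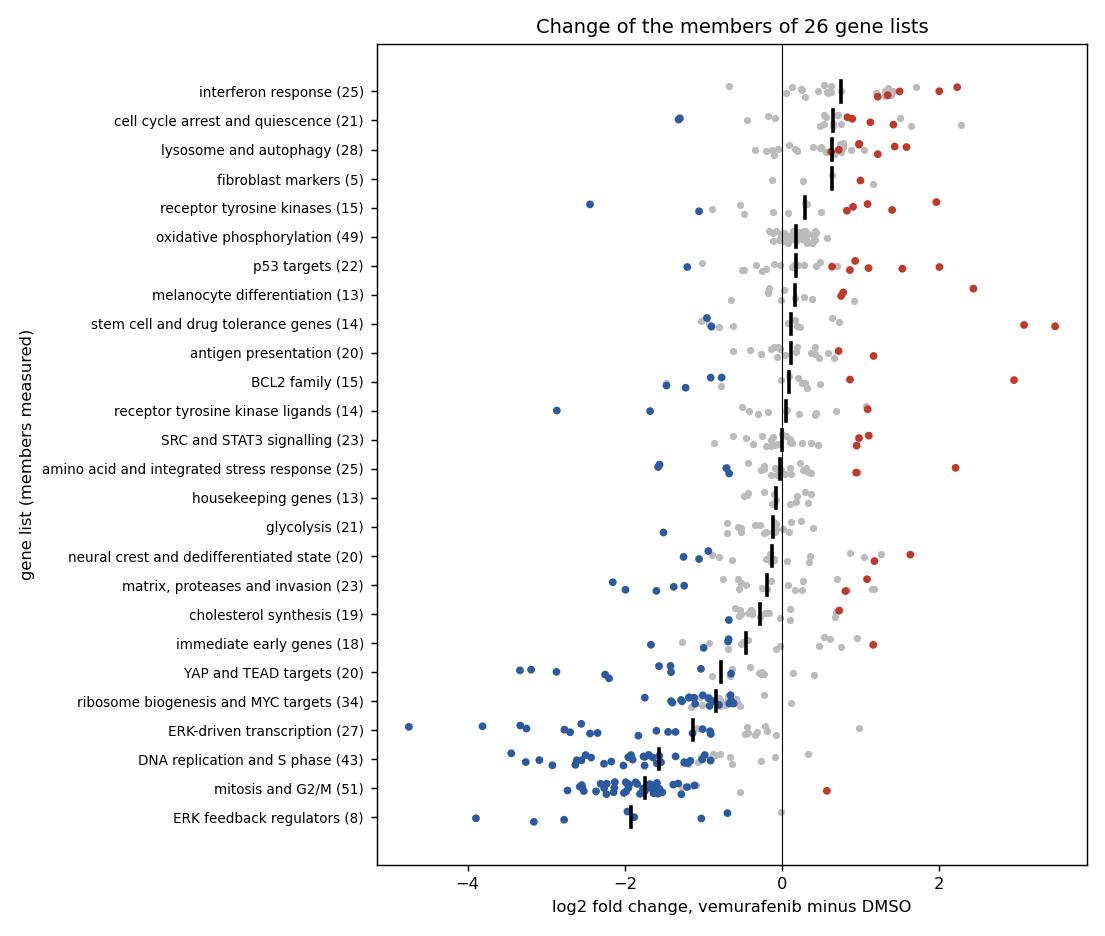
Log2 fold change, vemurafenib minus DMSO (horizontal axis), of each measured member of 26 gene lists (vertical axis, members measured in brackets), where red points rose and blue points fell at a limma adjusted p under 0.05, grey points did not pass, and black lines are list medians. The medians run from -1.92 for the ERK feedback regulators to 0.75 for the interferon response.

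Inhibitors of the cell cycle and genes of quiescence rose in part. Of 21 measured, 4 rose, 2 fell and 15 did not pass (15 rose and 3 fell when adjusted over the list alone; 13 rose and 2 fell with the replicate block). GAS1, a growth arrest gene, rose 2.67-fold and FOXO4, a forkhead factor, 2.18-fold, and TOB1 and FOXO3 rose by 0.83 and 0.89 on the log2 scale. The pocket protein RBL1 and the kinase inhibitor CDKN2D fell 2.49-fold and 2.46-fold. The limma adjusted p-values of GAS1, FOXO4, RBL1 and CDKN2D were 0.0338, 0.0290, 0.0120 and 0.00680. CDKN1A (log2 change 0.70, adjusted p = 0.0703) and CDKN1B (0.71, adjusted p = 0.0642) did not pass. The median was 0.65 (camera adjusted p = 0.0243; adjusted p = 0.524 with an estimated correlation). Of the 4 rises, 1 remained without DMSO 2, 10 were called without vemurafenib 2, and 0 without each of the other 4 arrays, where both falls kept their call. The rises were 0 with no filter, 8 with the trend and robust options, and 7 with no background correction, an offset of 50, median centring or the deposited log2 values.

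Among genes of cell death control, the BCL2 family changed in both directions. Of 15 measured, 2 rose, 4 fell and 9 did not pass (2 and 5 when adjusted over the list alone, 3 and 6 with the replicate block). BMF, a killer protein of the family, rose at least 6.63-fold (limma adjusted p = 7.93e-04), and BBC3, another, rose by 0.86 on the log2 scale. The killer protein PMAIP1 fell 2.77-fold, and the survival proteins BCL2 and MCL1 fell 2.34-fold and 1.88-fold (adjusted p-values of 0.0140, 0.0159 and 0.0140). The camera adjusted p was 0.704. Of 22 measured p53 targets, 6 rose, 1 fell and 15 did not pass (7 and 1 when adjusted over the list alone, 7 and 2 with the replicate block; camera adjusted p = 0.243). TP53INP1, TP53I3 and SESN1 rose by 2.00, 1.53 and 1.10 on the log2 scale, and the nuclease AEN fell 2.31-fold (adjusted p-values of 0.0105, 0.0133, 0.0288 and 0.0226). MDM2 (log2 change 0.13) and CDKN1A (0.70) did not pass. BMF and TP53INP1 passed without each array in turn, and the other 6 genes named by rule here did not (adjusted p up to 0.106). The 4 falls of the BCL2 family became 0, 2, 5, 1, 2 and 4, and the 6 rises of p53 targets 1, 2, 5, 1, 1 and 7, without DMSO unnumbered, 1 and 2 and vemurafenib unnumbered, 1 and 2 in turn.

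Growth factor receptors changed individually. Of 15 measured receptor tyrosine kinases, 5 rose, 2 fell and 8 did not pass (5 and 4 when adjusted over the list alone and with the replicate block; camera adjusted p = 0.647). PDGFRB, a receptor for platelet-derived growth factor, rose 3.89-fold from log2 6.62 ± 0.48 to 8.58 ± 0.37 (SD, n = 3 per group; limma adjusted p = 0.00824), the collagen receptor DDR1 2.64-fold (adjusted p = 0.00680) and the neuregulin receptor ERBB3 2.13-fold (adjusted p = 0.0195). EPHA2 fell 5.44-fold (adjusted p = 0.0113) and EGFR 2.08-fold (adjusted p = 0.0305). Of 14 measured ligands, the EGFR ligands TGFA and HBEGF fell 7.29-fold and 3.20-fold and the ephrin EFNA1 rose 2.13-fold, with 11 not passing, and the counts were the same when adjusted over the list alone (adjusted p-values of 0.00179, 0.00297 and 0.0263; camera adjusted p = 0.683). With the replicate block 3 ligands rose and 3 fell. The calls of PDGFRB, DDR1, TGFA and HBEGF held without each array in turn; EPHA2 lost its call without vemurafenib unnumbered (0.0558), EGFR without 4 arrays (up to 0.103) and with median centring, ERBB3 without 3 (up to 0.0842) and EFNA1 without 5 (up to 0.0954). The 5 rising receptors were 2, 2, 3, 2, 3 and 5 without DMSO unnumbered, 1 and 2 and vemurafenib unnumbered, 1 and 2 in turn.

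Targets of YAP and TEAD, factors that respond to cell shape and contact, fell in part. Of 20 measured, 10 fell and 10 did not pass (12 fell when adjusted over the list alone). NT5E fell 10.1-fold, the matricellular proteins CCN1 and CCN2 9.14-fold and 7.31-fold, and ANKRD1 4.76-fold (limma adjusted p-values of 5.49e-04, 0.00449, 0.00986 and 0.00680). The median log2 change was -0.78 (camera adjusted p = 9.10e-08; adjusted p = 0.128 with an estimated correlation). Leaving out vemurafenib unnumbered ended the call of CCN2 (0.0509) and left 6 of the 10 falls. Of 23 measured genes of matrix, proteases and invasion, 2 rose, 5 fell and 16 did not pass (4 and 8 when adjusted over the list alone; 5 and 6 with the replicate block; camera adjusted p = 0.127). The metalloproteinase inhibitor TIMP3 fell 4.45-fold, tissue plasminogen activator, PLAT, 3.98-fold, the urokinase receptor PLAUR 3.03-fold and the integrin ITGB3 at least 2.41-fold (adjusted p-values of 0.00783, 0.00515, 0.00680 and 0.00480). These 4 calls held without each array in turn, and the rises of COL5A1 (1.08) and ITGAV (0.81) did not; the matrix list passed without DMSO 2 (0.0453).

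Lineage genes moved individually. Of 13 measured melanocyte differentiation genes, 3 rose and 10 did not pass (4 rose when adjusted over the list alone, 4 rose and 1 fell with the replicate block; camera adjusted p = 0.342). GPNMB, a melanosomal glycoprotein, rose 5.40-fold, and the transcription factors TFAP2A and MITF rose 1.71-fold and 1.68-fold (limma adjusted p-values of 0.0450, 0.0327 and 0.0333). Of 20 measured genes of the neural crest and dedifferentiated state, 2 rose, 3 fell and 15 did not pass (5 and 6 when adjusted over the list alone and with the replicate block; camera adjusted p = 0.623). SNAI2 and ZEB2, repressors of epithelial genes, rose 3.10-fold and 2.26-fold, and TEAD4 fell 2.39-fold (adjusted p-values of 0.0139, 0.0490 and 0.0107). AXL (log2 change -0.90, adjusted p = 0.0533) and NGFR (-0.21) did not pass. Of 14 measured genes of stem cells and drug tolerance, CD24 and SOX2 rose, ALDH1A3, an aldehyde dehydrogenase, fell 1.94-fold and LIN28B, an RNA-binding protein, fell 1.86-fold (adjusted p-values of 0.0284 and 0.0150), and 10 did not pass (3 and 5 when adjusted over the list alone). This list's median was 0.12, its mean 0.24 and its camera direction down (adjusted p = 0.865), and 2 members rose and 5 fell with the replicate block. Of 23 measured genes of SRC and STAT3 signalling, BCL3, STAT3 and STAT5A rose 2.15-fold, 1.97-fold and 1.93-fold and 20 did not pass (3 rose and 1 fell when adjusted over the list alone, 3 and 2 with the replicate block; adjusted p-values of 0.0356, 0.0312 and 0.0322; camera adjusted p = 0.950). Apart from CD24, SOX2 and TEAD4, each call named here ended when at least 1 array was left out: those of GPNMB, TFAP2A, MITF, ALDH1A3, BCL3, STAT3 and STAT5A without any array but vemurafenib 2 (adjusted p up to 0.156), ZEB2 without any but DMSO 2 (up to 0.133), LIN28B without 3 arrays (up to 0.0663) and SNAI2 without vemurafenib 1 (0.0540). With no filter, 0 melanocyte and 0 SRC and STAT3 genes passed limma's test, and 1 neural crest gene rose and 1 fell.

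Some interferon-stimulated genes were higher in treated cells. Of 25 measured, 5 rose and 20 did not pass (9 rose when adjusted over the list alone; 14 rose and 1 fell with the replicate block). IRF9, a subunit of the interferon-activated transcription complex, rose by 2.23 on the log2 scale, the antiviral protein IFIT1 by 2.00, the ubiquitin-like ISG15 by 1.49 and IFI35 by 1.34 (limma adjusted p-values of 0.0178, 0.0325, 0.0428 and 0.0249). The median log2 change was 0.75 (camera adjusted p = 2.42e-04; adjusted p = 0.615 with an estimated correlation), or 1.42, 0.54 and 0.57 in the unnumbered, 1 and 2 pairs. Both samples numbered 2 lay below the others of their group over this list, by medians of 0.55 (DMSO) and 0.94 (vemurafenib) on the log2 scale. Leaving out DMSO unnumbered, vemurafenib unnumbered or vemurafenib 1 left 0 of the 5 rises, and leaving out DMSO 1, DMSO 2 and vemurafenib 2 gave 2, 3 and 13; without a filter 1 remained. Of 20 measured genes of antigen presentation, 2 rose, also when adjusted over the list alone, and 18 did not pass (camera adjusted p = 0.463). TAPBP, which loads peptides onto class I molecules, rose 2.24-fold and the proteasome subunit PSMB10 1.65-fold (adjusted p-values of 0.0198 and 0.0333); leaving out 3 and 5 arrays, respectively, ended their calls (up to 0.0860 and 0.125).

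Lysosomal and autophagy genes rose in part. Of 28 measured, 7 rose and 21 did not pass (10 rose when adjusted over the list alone and 17 with the replicate block). The lysosomal enzymes CTSA, CTSK and NEU1 rose 3.00-fold, 2.70-fold and 2.33-fold, and the autophagosome protein GABARAPL1 1.97-fold (limma adjusted p-values of 0.0330, 0.0397, 0.0290 and 0.0161). The median log2 change was 0.64 (camera adjusted p = 2.42e-04; adjusted p = 0.579 with an estimated correlation). Both samples numbered 2 lay below the others of their group, by medians of 0.26 (DMSO) and 0.42 (vemurafenib). The 7 rises became 0, 0, 2, 0, 1 and 13 without DMSO unnumbered, 1 and 2 and vemurafenib unnumbered, 1 and 2 in turn, and 2 without a filter.

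Metabolic and stress genes changed individually. Of 21 measured glycolysis genes, hexokinase HK2 fell 2.86-fold (limma adjusted p = 0.00786) and 20 did not pass, with the same count when adjusted over the list alone and 3 falling with the replicate block. The list's median was -0.11 (camera adjusted p = 0.0740), and the list passed at 0.00933 with median centring, at 0.0419 with no background correction, at 0.0477 with an offset of 50, at 0.0432 with the deposited log2 values, at 5.94e-04 without DMSO 2, at 0.0124 without vemurafenib 1 and at 0.0179 without both samples numbered 2. Of 49 measured genes of oxidative phosphorylation, 0 passed limma's test, over all genes or adjusted over the list alone, and 4 had an unadjusted p under 0.05 (with the replicate block 1 rose); the most abundant were ATP5F1B (log2 change -0.02) and COX7C (0.29). Their median of 0.18 passed with camera (adjusted p = 0.0336; adjusted p = 0.699 with an estimated correlation), but not with the replicate block (0.0586), with median centring (0.319), or without DMSO 2 (0.137), vemurafenib unnumbered (0.0531), vemurafenib 2 (0.0982) or both samples numbered 2 (0.202). Of 19 measured genes of cholesterol synthesis, SC5D rose 1.65-fold and EBP fell 1.60-fold (adjusted p-values of 0.0269 and 0.0476; camera adjusted p = 0.213), with 1 rise and 0 falls when adjusted over the list alone and 3 and 2 with the replicate block; each call ended without at least 4 arrays, and the list passed without DMSO 2 (0.00399) and without both samples numbered 2 (0.0320). Over the glycolysis and cholesterol lists the DMSO sample 2 lay below the other controls by medians of 0.58 and 0.80. Of 25 measured genes of the amino acid and integrated stress response, 2 rose, 4 fell and 19 did not pass, also when adjusted over the list alone (camera adjusted p = 0.458). NUPR1, a stress-induced chromatin protein, rose 4.62-fold and the tRNA synthetase WARS1 1.92-fold, while the secreted STC2 fell 2.98-fold and the mitochondrial folate enzyme MTHFD2 2.95-fold (adjusted p-values of 0.0312, 0.0242, 0.00623 and 0.0181). Of these, STC2 passed without each array in turn (the others up to 0.120), and of the 2 rises and 4 falls 0 and 1 remained without either unnumbered sample or vemurafenib 1, and 0 and 2 without DMSO 1.

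**Figure D3:**
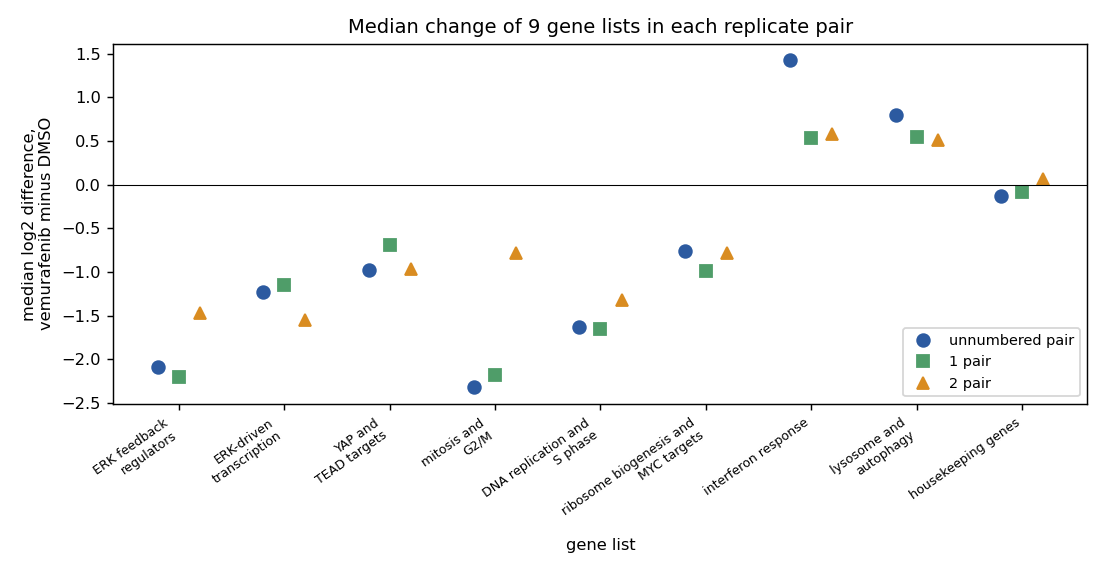
Median log2 difference, vemurafenib minus DMSO (vertical axis), of 9 gene lists (horizontal axis) in the unnumbered (circles), 1 (squares) and 2 (triangles) replicate pairs; each point is a median over the measured members of a list. The ERK lists lie below 0 in each pair, while the mitosis list lies at -2.32, -2.18 and -0.78.

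Markers of other cell types and control genes were measured for comparison. Of 5 fibroblast markers, the matrix proteoglycan DCN rose (at least 1.93-fold, limma adjusted p = 0.0231) and 4 did not pass; 3 rose when adjusted over the list alone and with the replicate block (camera adjusted p = 0.123). The endothelial receptor ROBO4, the 1 endothelial marker measured, fell 2.03-fold (adjusted p = 0.0209, and also when adjusted over the list alone). Leaving out 4 arrays ended the call of DCN (up to 0.0823) and leaving out 3 that of ROBO4 (up to 0.0787). For 4 keratinocyte markers, with KRT10 and DSP the most abundant (log2 changes of 0.27 and 0.33), 0 passed limma's test and 1 had an unadjusted p under 0.05. For 3 leukocyte markers, with CD68 and LYZ the most abundant (0.69 and -0.27), both counts were 0; CD68 passed with the replicate block. Of 13 housekeeping genes, 0 passed and 1 had an unadjusted p under 0.05, with log2 changes of -0.13 ± 0.19 (SE) for ACTB, -0.10 ± 0.15 for GAPDH and -0.08 ± 0.14 for EEF1A1 and a camera adjusted p of 0.683. For these 3 lists the counts were also 0 when adjusted over the list alone.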

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

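The count of unnamed probes below was examined after the main comparison had been made. Probes without a single gene symbol in the annotation were left out of every gene count, yet 212 of them were higher and 209 lower in vemurafenib at a limma adjusted p under 0.05, against no drug in the controls. This is 10.3% of the 4079 unnamed probes that were kept, against 15.6% of the named probes. Which transcripts these probes measure was not analysed here.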

How the results depend on the processing

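The averaging of samples and the removal of both samples numbered 2 were chosen after the data were seen; the other alternatives were fixed beforehand. CD24 and SOX2 passed limma's test under each of the 18 alternatives run for them, with log2 changes of 2.07 to 3.88 (adjusted p 4.23e-04 to 0.0388) and 2.39 to 3.27 (adjusted p 2.17e-04 to 0.0462). No result that passed in either setting changed direction, and genes chosen from these same arrays could hardly do so. The count of changed genes moved by over 1.5 times with no filter (944, where 48103 probes share the adjustment), with the replicate block (3344), at an adjusted p under 0.01 (267), without both samples numbered 2 (3649), with the unnumbered and 1 samples averaged (26, with 2 samples against 2), and over single arrays left out (307 to 2670). The count of genes changed at least 2-fold was 453 with no background correction, 552 with an offset of 50 and 459 with the deposited log2 values, settings that compress folds of dim genes. It was 532 with no filter, 624 with treat, 26 with averaging, and 305 to 1526 over single arrays left out. With no filter, the rises in the immediate early, ligand, stress response and matrix lists also lost their calls. Of the 10 lists called by camera, 1 passed with an estimated correlation. Fry called 5 lists: 3 of those 10, and melanocyte differentiation (0.00987) and the matrix list (0.0337), which camera did not call; the other list counts ran from 9 to 12. The replicate block ended the call of 1 list, oxidative phosphorylation, began that of CD68, and changed no other call of a list or named gene; it moved counts within lists, and those moved by over 1.5 times stand in the report. Of 1226 comparisons of named genes other than CD24 and SOX2 with all other settings, 1078 kept their call, 147 lost it and 1 gained it; over single arrays left out, 397 of 624 kept it and 227 lost it. For lists, 336 of 363 and 149 of 156 kept it. Where no cause is given here, the cause was not tested. The slide as a block was not run because the tables used give no slide. Signals near background limit the folds of dim genes.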

Other observations

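The genes in the next paragraph, the list of histone genes and its tests, and the tests of mixing and compression were chosen after results were seen. The other splits of the samples were planned beforehand.

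Further single genes outside the lists changed strongly; they are examples taken from the highest ranks, and no group of them was tested. The epithelial keratins KRT15 and KRT13 rose by 2.41 ± 0.28 (log2 change ± SE) and at least 4.64-fold (limma adjusted p-values of 0.00392 and 0.0183), and the mucin MUC1 by 2.48 ± 0.59 (0.0323). The aldo-keto reductase AKR1B10 rose at least 5.42-fold, with log2 rises for AKR1C4 of 2.24, for ALDH3B1 of 2.38, CYP1B1 of 2.33, the retinoic acid carrier CRABP2 of 2.22 and HMOX1 of 2.31 (adjusted p-values of 5.98e-04, 0.00203, 0.0120, 0.0139, 0.00820 and 0.0277). Genes that fell include the activin antagonist FST (log2 change -2.74), IGFBP3 (-2.70), the WNT antagonist SFRP1 (-2.35) and ANGPTL4 (-2.80; adjusted p-values of 0.00222, 0.00768, 0.00123 and 0.0420). The fall of ANGPTL4 was uneven (SE 0.73), with log2 differences of -4.49, -3.03 and -0.90 in the unnumbered, 1 and 2 pairs. The crosslinking enzyme TGM2 and the peroxisomal oxidase ACOX2 changed by -3.15 and -3.23 (0.00127 and 5.98e-04), and SOX11, another SOX factor, by -2.28 (0.00217), while SOX2 rose.

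When the 6 arrays were split in all 10 ways into 3 and 3, 1 split, the real one, gave 1800 or more genes. The highest of the other splits gave 0 genes with limma (59 to 1048 at an unadjusted p under 0.05). Each of these splits mixes treated and control samples, so the difference between the groups adds to the spread and lowers the count. The 0 therefore says nothing about false calls in the real split. Among the 4 splits that part all 3 replicate pairs, the 3 that mix the groups gave 0 genes (73, 78 and 211 unadjusted). The splits are too few for a share under 0.05.

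The mitosis genes fell less in the replicate 2 pair (median log2 -0.78) than in the unnumbered (-2.32) and 1 (-2.18) pairs. Control RNA or untreated cells mixed into the vemurafenib sample 2 would need a share of 37.1% ± 2.05 (bootstrap SE over genes) of control signal. This share was computed over 94 genes of the mitosis and S phase lists together. But of 4453 genes with a control level of at least 8 (log2), 28 lay below that share by more than 2 residual SDs, 27 of them detected in that sample. ETV4 stood at 4.56%, CXCL8 at 5.36% and NT5E at 5.43% of their control level, which argues against such mixing. A signal on the arrays numbered 2 compressed as much as the mitosis fall would shrink the fall of the ERK lists to -0.48. Their median in that pair was -1.55, 0.20 being the bootstrap SE of the difference over genes, which argues against compression of that size. Milder compression was not tested, and this SE does not measure the spread between arrays. The median of the feedback regulators fell less in that pair (-1.47 against -2.09 and -2.21), and that of ERK-driven transcription fell more (-1.55 against -1.23 and -1.16). This median does not describe each member. CXCL8 (-3.94 against -5.19 and -5.11), FOSL1 (-2.64 against -4.19 and -4.60) and ETV5 (-3.02 against -3.25 and -3.48) fell less in that pair. ETV4 fell more (-3.50 against -3.24 and -3.25). A difference in growth state, harvest or batch may remain, but the design holds no group that bears on it, so no biological explanation was tested.

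The signals of some histone genes rose while those of S phase genes fell, a pattern noticed from H2BC5 and H2AC18 among the highest ranks. Of 32 measured histone genes, 15 rose, 17 did not pass (H4C3 and H1-10 with log2 changes of -1.17 and -0.54), and the median was 0.87; with no background correction 12 rose and 2 fell (median 0.35), and over single arrays left out between 2 (without vemurafenib unnumbered) and 18 (without vemurafenib 2) rose. Without the 2 genes that prompted the list, 13 of 30 rose (median 0.81, camera p = 1.02e-05; p = 0.0653 with an estimated correlation). If this rise followed the size of the cell cycle fall, it should be smaller in the replicate 2 pair, where the log2 difference to the other pairs was -0.58 (bootstrap SE over genes 0.27), but -0.41 (0.29) without those 2 genes, which is under 2 SEs, so the hypothesis stays open. Genes within a core histone class are near-identical copies whose probes may share signal, and probe sequences were not used here. Which forms of histone RNA the arrays capture was not examined either. The number of histone genes whose RNA rose therefore stays open.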
